A study of Mus musculus with 12 samples.

How the data were processed

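Gene expression was measured by RNA sequencing of total RNA from fresh ventricle tissue of mouse hearts in 12 libraries, 3 each of WT females, WT males, LCHADD females and LCHADD males. Per the labels' protocols, RNA was extracted with a column kit for fibrous tissue and the libraries were sequenced on a NovaSeq 6000, and no treatment is named. The deposited table holds 1 signal value per gene and library, which is the gene's read count divided by 1 size factor per library. Per the submitters' processing notes, the reads were processed against genome build GRCm39 with bcl2fastq and DESeq2, without versions. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. The unit was tested on the values: in every library 100.0% of the values were whole multiples of 1 step, within 0.01 of a whole number, so whole reads were recovered as the value divided by the step. The table has 51912 Ensembl gene IDs, of which 51633 were matched to a symbol and 279 were not. Symbols, and the order of genes along chromosomes, came from GENCODE vM21 on build GRCm38, so symbols are those of that release and no coordinates are given. Genes that overlap or have close copies, such as Gsta1, Acot2 and the globin genes, are uncertain because the counting is not described.

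Libraries were grouped by the genotype and sex in their labels. The deposited values were used with the authors' scaling, as log2 of the value plus 1, for genes with at least 10 in at least 3 of the 12 libraries. This left 13865 genes, 22 of them without a symbol, of 25687 with any read, and they held 99.9% of the reads. They were tested in 1 fit with 4 group means with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3. The comparisons were LCHADD against WT in females, in males and in the mean of both sexes, the interaction of genotype and sex, and females against males within each genotype. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Limma's adjusted p is meant wherever no other tool is named. Changes are LCHADD minus WT, or female minus male, on the log2 scale, with the SE of the fit. Changes of genes with few reads in a group depend on the added 1. For genes with 1 to 3 reads in a group, the ratio of normalised reads is given with an exact (Clopper-Pearson) 95% interval, which covers counting error and no other.

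Before the data were examined, 50 lists of genes were fixed (pathways, cell type markers, technical and sex-linked genes), and 44 with at least 4 tested members were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Beside it, camera was run with a correlation estimated from the data. Fry was run too, whose directional test and test for change in either direction do not compare a list with other genes. Counts of list members use the adjustment over all tested genes, and a further count uses the adjustment over the list alone. Several lists share genes. The genes to be named were fixed by a rule at the same time. It takes Hadha and Hadhb, and, for each genotype comparison, the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 50, did not overlap between the groups and had a symbol that is not a clone name. For each list it takes up to 4 members with the smallest adjusted p that passed and up to 2 of the most abundant that did not, in each comparison. For the interaction and the sexes it takes up to 5 genes per direction and the sex-linked lists. Some genes that the rule takes are not reported here.

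The libraries held 15.6 to 23.2 M reads (M, mega) assigned to genes. The method was tested on simulated counts for 13865 genes drawn from the means and library sizes of these samples, with 200 genes changed. In the female comparison 46.3% of the 1.5-fold changes, 77.6% of the 2-fold and 97.0% of the 4-fold changes passed, and 6.96% of the genes that passed were unchanged ones. For males the shares were 47.8%, 80.6% and 93.9%, and for the interaction 20.9%, 59.7% and 83.3%. A list of 28 genes that all moved by 1.5-fold passed all 3 list tests in each comparison, and 0 of the 42 lists left unmoved passed. Simulated genes were drawn independently, while in these data the estimated inter-gene correlation reached 0.84 (erythroid markers). So lists whose genes vary together were not simulated, and the shares may not hold where more or fewer genes pass.

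The alternatives were other added values (5 and 0.5), no filter and a filter at 50, TMM and upper-quartile scaling, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) on the recovered reads, robust eBayes, array quality weights, the groups of a comparison alone in the fit, the replicate number as a block, each library left out in turn, and a threshold of 1.5-fold besides the adjusted p. Scaling by the reads from nuclear genes, and leaving out WT female 3 with LCHADD female 2, were chosen after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Reads were not realigned, and no splice form or variant was examined.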

Results

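RNA from fresh heart ventricle tissue of mice was sequenced in 12 libraries, 3 for each of 4 groups: wild-type (WT) females, WT males, LCHADD females and LCHADD males. LCHADD stands for long-chain 3-hydroxyacyl-CoA dehydrogenase deficiency, a defect of the mitochondrial trifunctional protein that breaks down long-chain fatty acids. The labels name no treatment and give no age, strain or hour of collection. The libraries held 15.6 to 23.2 M reads (M, mega) assigned to genes. The group means were 21.6 ± 1.37 M in WT females, 18.6 ± 2.84 M in WT males, 18 ± 1.19 M in LCHADD females and 18.1 ± 0.702 M in LCHADD males (SD, n = 3). Mitochondrially encoded genes took 29.3 ± 1.94% of the reads in WT and 34.4 ± 2.70% in LCHADD (SD, n = 6), with the highest share, 37.9%, in LCHADD female replicate 3. In a principal component analysis of the 13865 tested genes, the component with the largest share of the variance, 50.9%, separated the 6 LCHADD from the 6 WT libraries, and the next, 12.3%, separated the sexes.

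Hadha and Hadhb encode the alpha and beta subunits of the trifunctional protein, and Hadha carries the long-chain 3-hydroxyacyl-CoA dehydrogenase activity. Hadha (ENSMUSG00000025745) had 22401, 21430 and 23126 normalised read counts in WT females 1, 2 and 3, 25688, 25456 and 23343 in LCHADD females, 25845, 24116 and 23402 in WT males and 28083, 27817 and 27283 in LCHADD males. Its log2 change, LCHADD minus WT, was 0.15 in females (SE 0.07, limma adjusted p = 0.11), 0.18 in males (adjusted p = 0.093) and 0.17 in the mean of both sexes (SE 0.05, adjusted p = 0.013). The labels do not say how the gene was altered, and a read count does not see a change of sequence, so the level of Hadha does not check the genotype labels. Hadhb (ENSMUSG00000059447) rose from 33832 ± 1197 to 40089 ± 1924 in females (log2 change 0.24, SE 0.07, adjusted p = 0.015) and from 35382 ± 1371 to 42639 ± 798 in males (log2 change 0.27, adjusted p = 0.018). The sex labels were checked with Xist, transcribed from the inactive X chromosome, and with 4 genes of the Y chromosome. Xist had 1950 to 4588 normalised reads in the 6 female libraries and 0 to 9.38 in the 6 male libraries. Ddx3y, Eif2s3y, Uty and Kdm5d had 0 reads in all 6 female libraries and 239 (Kdm5d) to 1547 (Ddx3y) normalised reads in the male libraries.

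The comparison of LCHADD with WT females asks how the ventricle's transcripts differ when long-chain fatty acid oxidation is impaired. Enzymes that make serine, one-carbon units and asparagine stood among the largest rises. Mthfd2, a mitochondrial enzyme of folate metabolism, rose from 35.7 ± 2.34 to 5218 ± 943 normalised reads (log2 change 7.14, SE 0.26, adjusted p = 2.8e-10). Asns, asparagine synthetase, rose from 28.6 ± 6.71 to 2603 ± 832 normalised reads (log2 change 6.43, SE 0.27, adjusted p = 9.5e-10), and Phgdh, the entry enzyme of serine synthesis, rose from 14.4 ± 1.33 to 1257 ± 189 normalised reads (log2 change 6.34, SE 0.19, adjusted p = 1.7e-11). Fgf21, a secreted metabolic hormone, rose from 1.09 ± 0.949 to 304 ± 241 normalised reads (adjusted p = 5.4e-07), and Ostn, which encodes the peptide osteocrin, rose from 2.26 ± 3.26 to 1187 ± 648 normalised reads (adjusted p = 1.4e-07). Slc7a11, the cystine transporter, and Soat2, which makes cholesterol esters, rose from 1.12 ± 1.32 to 234 ± 184 normalised reads and from 1.59 ± 2.06 to 322 ± 178 normalised reads (adjusted p = 6.2e-07 and 7.0e-07). Other rises were near 0 in WT. Vmn2r3, of a family of vomeronasal receptors, had 3330 reads against 1 read over the 3 WT libraries, a ratio of 4146 (95% counting interval 744 to 163800), and Slc7a3, a transporter of cationic amino acids, had 656 reads against 3 reads over the 3 WT libraries, a ratio of 272 (95% counting interval 92.8 to 1324). Serpinb1c, a protease inhibitor, rose from 1.38 ± 0.451 to 189.5 ± 108 normalised reads (adjusted p = 3.4e-06).

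Among the largest falls in females, Pla2g5, a secreted phospholipase, fell from 923 ± 89.2 to 43.2 ± 32.6 normalised reads (log2 change -4.94, SE 0.56, adjusted p = 1.2e-05). Phkg1, the catalytic subunit of muscle phosphorylase kinase, fell from 357 ± 62.4 to 31.1 ± 21.7 normalised reads (log2 change -3.67, SE 0.35, adjusted p = 2.5e-06), and Clcn1, a chloride channel, fell from 142 ± 14.9 to 8.80 ± 12.5 normalised reads (log2 change -4.74, SE 0.60, adjusted p = 3.3e-05). Cenpf (-4.73, SE 0.47), the transcription factor Snai3 (-3.26, SE 0.35), the kinase Sbk2 (-3.25, SE 0.35), Cntn2, a cell adhesion molecule of the conduction system (-3.06, SE 0.35), Cyp26b1, which breaks down retinoic acid (-2.86, SE 0.38), and Adam11 (-2.76, SE 0.22) also fell on the log2 scale. In all, 4692 of 13865 genes passed in females, 2314 higher and 2378 lower in LCHADD, and 2461 of them differed by at least 1.5-fold. An unadjusted p under 0.05 was found for 6002 genes. With the female libraries alone in the fit fewer genes passed. Scaling by reads from nuclear genes gave 4824 genes, 2873 higher and 1951 lower. Without LCHADD female 2 and WT female 3, an alternative chosen after the data were seen, 3749 genes passed.

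In males the same comparison gave rises of the same enzymes. Mthfd2 rose from 37.3 ± 20.3 to 3208 ± 695 normalised reads (log2 change 6.49, SE 0.26, adjusted p = 1.1e-09), Asns rose from 28.6 ± 9.24 to 1340 ± 254 normalised reads (log2 change 5.54, SE 0.27, adjusted p = 8.4e-09) and Phgdh rose from 19.5 ± 1.43 to 805 ± 209 normalised reads (log2 change 5.27, SE 0.19, adjusted p = 2.7e-10). Fgf21 rose from 1.56 ± 1.91 to 147 ± 13.6 normalised reads (adjusted p = 6.2e-06), Soat2 rose from 1.69 ± 1.46 to 141 ± 53.9 normalised reads (adjusted p = 1.6e-05), and the transcription factor gene Tfcp2l1 rose from 18.8 ± 5.33 to 382 ± 42.3 normalised reads (adjusted p = 7.3e-08). Near 0 in WT males were Vmn2r3, with 1269 reads against 1 read over the 3 WT libraries, a ratio of 1390 (95% counting interval 249 to 54960), Ostn, with 927 reads against 3 reads over the 3 WT libraries, a ratio of 339 (95% counting interval 116 to 1645), Slc7a11, with 269 reads against 1 read over the 3 WT libraries, a ratio of 295 (95% counting interval 52.5 to 11680), and Slc7a3, with 219 reads against 1 read over the 3 WT libraries, a ratio of 240.0 (95% counting interval 42.6 to 9521). Among the largest falls were those of Pla2g5 (log2 change -3.19, SE 0.56), Phkg1 (-2.95, SE 0.35), Cenpf (-2.64, SE 0.47) and Sbk2 (-2.63, SE 0.35). Armh4 (-2.39, SE 0.40), Cyp26b1 (-2.29, SE 0.38), Cntn2 (-2.23, SE 0.35), Ramp1, a subunit of the receptor for calcitonin gene-related peptide (-2.23, SE 0.35), and Clcn1 (-2.13, SE 0.60) fell too. In males 2146 genes passed, 1069 higher and 1077 lower in LCHADD, 1087 of them by at least 1.5-fold, and 4120 had an unadjusted p under 0.05. The count moved with single libraries, to 1332 without WT male 1, 1317 without WT male 3, 1317 without LCHADD male 1 and 3293 without LCHADD female 2, which enters through the shared estimate of the spread. With the 6 male libraries alone in the fit it was 3342, with array quality weights 3601, and without both LCHADD female 2 and WT female 3 3317.

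Averaged over both sexes, 5661 genes passed, 2808 higher and 2853 lower in LCHADD, 2033 of them by at least 1.5-fold, with 6809 at an unadjusted p under 0.05. Scaling by reads from nuclear genes gave 5758 genes, 3306 higher and 2452 lower. Mthfd2 changed by 6.81 (SE 0.19) on the log2 scale, Asns by 5.98 (SE 0.19), Phgdh by 5.80 (SE 0.13) and Psat1, the next enzyme of serine synthesis, by 4.92 (SE 0.27). Psat1 went from 40.1 ± 17.4 to 2140 ± 1303 normalised reads in females and from 34.9 ± 3.54 to 699.7 ± 196 in males. On the falling side stood Pla2g5 at -4.07 (SE 0.40), Cenpf at -3.68 (SE 0.34) and Clcn1 at -3.43 (SE 0.43). Of the 44 lists of genes that could be tested, 25 passed camera with its preset correlation in females (5 higher, 20 lower), 23 in males (7 higher, 16 lower) and 26 in the mean of both sexes (5 higher, 21 lower). With a correlation estimated from the data no list passed in any of these comparisons, the lowest adjusted p being 0.22 in females, 0.18 in males and 0.25 in the mean. The directional test fry, which does not compare a list with other genes, passed 32 lists in females, 20 in males and 31 in the mean, and its test for change in either direction passed 41, 36 and 42. Of the lists that passed camera, all 25 in females, 17 of 23 in males and all 26 in the mean also passed fry. In the accounts of the lists, the values after a gene symbol are its log2 changes in females and then in males with their SE, and n.s. marks one that did not pass.

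**Figure D1:**
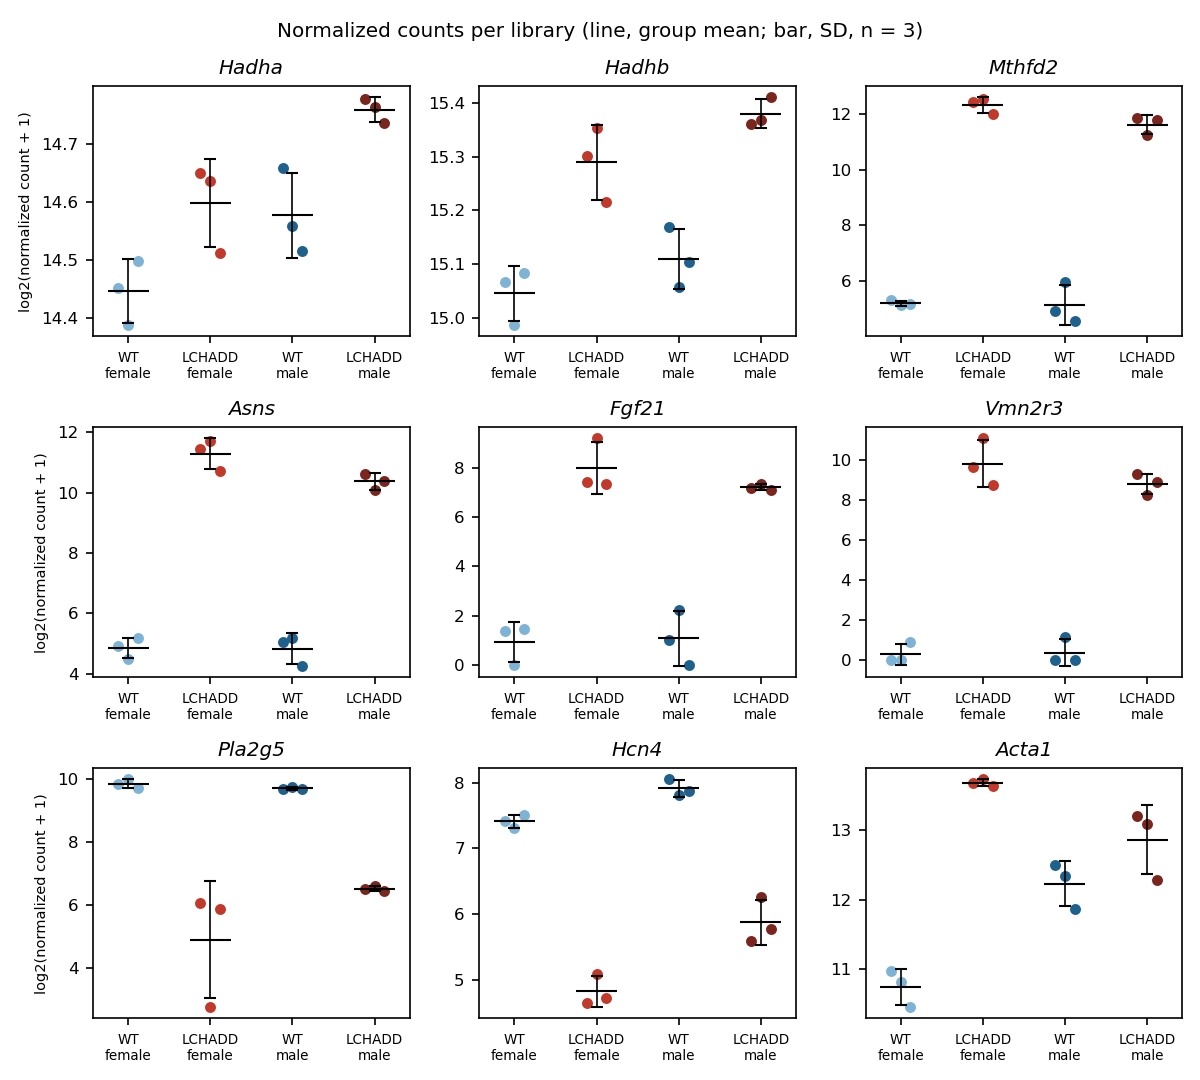
Normalised read counts of 9 genes in the 12 libraries, on a log2 axis after adding 1, with group means (lines), SD (bars, n = 3) and a separate axis for each gene. The 6 LCHADD libraries lie above the 6 WT libraries for Mthfd2, Asns, Fgf21 and Vmn2r3 and below them for Pla2g5 and Hcn4.

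The integrated stress response, a programme of amino acid and one-carbon genes switched on by the transcription factor ATF4, had 28 tested genes, of which 23 rose and 1 fell in females (25 passing adjusted over the list alone) and 21 rose and 0 fell in males (24 passing). By camera the stress response list ranked above the other genes in females (adjusted p = 1.1e-18, or adjusted p = 0.22 with an estimated correlation) and in males (adjusted p = 5.2e-22, or adjusted p = 0.18 with an estimated correlation). Besides Mthfd2, Asns and Phgdh, the transcription factor gene Atf5 (3.47 and 3.18, SE 0.18) rose in both sexes, while Ddit4 (-0.55 n.s. and -0.54 n.s., SE 0.27) and Stc2 (0.01 n.s. and -0.35 n.s., SE 0.16) did not pass. The group of mitochondrial chaperones and proteases had 14 tested genes, of which 8 rose and 1 fell in females (9 passing adjusted over the list alone) and 4 rose and 1 fell in males (7 passing). By camera the chaperone list ranked above the other genes in females (adjusted p = 0.0051, or adjusted p = 0.36 with an estimated correlation) and in males (adjusted p = 0.0086, or adjusted p = 0.46 with an estimated correlation). The protease Lonp1 (1.80 and 1.21, SE 0.16), the chaperonin partners Hspe1 (1.36 and 0.55, SE 0.14) and Hspd1 (0.87 and 0.58, SE 0.12) and the mitochondrial heat shock protein gene Hspa9 (1.04 and 0.84, SE 0.13) rose, and the protease Spg7 (-0.72 and -0.30, SE 0.07) fell. Endoplasmic reticulum chaperones had 18 tested genes, of which 1 rose and 4 fell in females (5 passing adjusted over the list alone) and 2 rose and 0 fell in males (1 passing). The reticulum list did not pass camera in females (adjusted p = 0.47) or in males (adjusted p = 0.55). Here Herpud1 (0.56 and 0.48, SE 0.07) rose, and the abundant chaperone Hspa5 (-0.70 and -0.14 n.s., SE 0.14) was lower in females. NRF2 targets and other genes of the oxidative stress response had 22 tested genes, of which 17 rose and 3 fell in females (20 passing adjusted over the list alone) and 10 rose and 2 fell in males (17 passing). By camera the NRF2 list ranked above the other genes in females (adjusted p = 7.4e-06, or adjusted p = 0.22 with an estimated correlation) and in males (adjusted p = 1.1e-04, or adjusted p = 0.23 with an estimated correlation). Examples were Gsta1 (3.48 and 2.80, SE 0.29), Gpx4 (0.66 and 0.37, SE 0.08), Sod1 (0.61 and 0.38, SE 0.08) and Hmox1 (1.52 and 0.51 n.s., SE 0.21), of which Gsta1 has a close copy, Gsta2, whose reads the counting may have shared. Heat shock genes had 11 tested genes, of which 6 rose and 0 fell in females (6 passing adjusted over the list alone) and 3 rose and 0 fell in males (5 passing). By camera the heat shock list ranked above the other genes in males (adjusted p = 0.027, or adjusted p = 0.46 with an estimated correlation) and did not pass in females (adjusted p = 0.10). Members that rose included Hsp90ab1 (0.59 and 0.49, SE 0.08), Hspa4l (0.43 and 0.30, SE 0.07) and Hspa8 (0.38 and 0.39, SE 0.09).

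Mitochondrial fatty acid oxidation, the pathway of Hadha and Hadhb, had 22 tested genes, of which 3 rose and 7 fell in females (10 passing adjusted over the list alone) and 2 rose and 1 fell in males (3 passing). The fatty acid oxidation list did not pass camera in females (adjusted p = 0.44) or in males (adjusted p = 0.96). The enzymes of shorter acyl chains Acads (-0.58 and -0.30, SE 0.08), Acaa2 (-0.56 and -0.25 n.s., SE 0.08) and Hadh (-0.46 and -0.20 n.s., SE 0.08) were lower in females, while Cpt1a (0.62 and 0.45, SE 0.13), a carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose. The abundant genes Acsl1 (-0.13 n.s. and 0.03 n.s., SE 0.08) and Acadl (0.10 n.s. and 0.11 n.s., SE 0.06) did not pass. Genes that respond to the nuclear receptor PPARalpha had 21 tested genes, of which 11 rose and 2 fell in females (14 passing adjusted over the list alone) and 8 rose and 2 fell in males (12 passing). By camera the PPARalpha list ranked above the other genes in females (adjusted p = 0.0065, or adjusted p = 0.43 with an estimated correlation) and in males (adjusted p = 0.0010, or adjusted p = 0.46 with an estimated correlation). Besides Fgf21, Pdk4 (2.13 and 2.28, SE 0.38), which restrains pyruvate oxidation, and Acot2 (2.40 and 1.61, SE 0.34) and Fabp3 (0.61 and 0.35, SE 0.10) rose, the lipoprotein receptor Vldlr (-0.68 and -0.30, SE 0.10) fell, and Cd36 (0.07 n.s. and 0.03 n.s., SE 0.08) did not pass. Acot2 has a close copy, Acot1. WT female 3 had the highest mean of this list among WT females, 0.47 on the log2 scale relative to the WT female mean. Peroxisomal fatty acid oxidation had 20 tested genes, of which 7 rose and 4 fell in females (11 passing adjusted over the list alone) and 3 rose and 3 fell in males (7 passing). The peroxisomal list did not pass camera in females (adjusted p = 0.63) or in males (adjusted p = 0.59). Catalase, Cat (0.96 and 0.73, SE 0.13), and Hsd17b4 (0.39 and 0.35, SE 0.09) rose, and Scp2 (-0.59 and -0.36, SE 0.08) and Phyh (-0.45 and -0.25, SE 0.07) fell. Lipid droplet and triglyceride metabolism had 22 tested genes, of which 7 rose and 6 fell in females (13 passing adjusted over the list alone) and 2 rose and 3 fell in males (7 passing). The lipid droplet list did not pass camera in females (adjusted p = 0.83) or in males (adjusted p = 0.96). Lipoprotein lipase, Lpl (-0.70 and -0.14 n.s., SE 0.09), and Fitm1 (-1.73 and -0.88, SE 0.23) and Lpin1 (-0.93 and -0.42, SE 0.13) were lower, Agpat2 (0.68 and 0.57, SE 0.12) was higher, and the triglyceride lipase Pnpla2 (0.03 n.s. and 0.07 n.s., SE 0.13) did not pass.

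Lipid and sterol synthesis had 22 tested genes, of which 3 rose and 5 fell in females (8 passing adjusted over the list alone) and 4 rose and 4 fell in males (10 passing). The sterol list did not pass camera in females (adjusted p = 0.60) or in males (adjusted p = 0.59). Malic enzyme, Me1 (1.01 and 0.56, SE 0.10), and Cyp51 (0.69 and 0.60, SE 0.13) rose, and Srebf1 (-0.87 and -0.49, SE 0.13) and Scd2 (-0.83 and -0.87, SE 0.17) fell. Cardiolipin synthesis and remodelling had 12 tested genes, of which 2 rose and 3 fell in females (5 passing adjusted over the list alone) and 0 rose and 3 fell in males (3 passing). The cardiolipin list did not pass camera in females (adjusted p = 0.83) or in males (adjusted p = 0.44). Falls were those of Abhd18 (-1.17 and -0.66, SE 0.15), Lclat1 (-0.67 and -0.41, SE 0.09) and Taz (-0.46 and -0.29, SE 0.08), the last of which encodes the cardiolipin transacylase tafazzin. Glycolysis and glucose uptake had 24 tested genes, of which 6 rose and 9 fell in females (15 passing adjusted over the list alone) and 5 rose and 2 fell in males (10 passing). The glycolysis list did not pass camera in females (adjusted p = 0.24) or in males (adjusted p = 0.38). Lactate dehydrogenase, Ldha (-1.23 and -0.63, SE 0.12), enolase, Eno3 (-1.40 and -0.51 n.s., SE 0.17), and the glucose transporter Slc2a4 (-0.80 and -0.28 n.s., SE 0.10) were lower, Pfkp (0.99 and 0.61, SE 0.11), Hk1 (0.54 and 0.65, SE 0.11) and Pgk1 (0.44 and 0.28, SE 0.07) were higher, and Gapdh (-0.04 n.s. and 0.03 n.s., SE 0.08) did not pass. Pyruvate dehydrogenase and the tricarboxylic acid cycle had 29 tested genes, of which 1 rose and 12 fell in females (13 passing adjusted over the list alone) and 0 rose and 5 fell in males (6 passing). By camera the tricarboxylic acid list ranked below the other genes in females (adjusted p = 3.4e-04, or adjusted p = 0.36 with an estimated correlation) and did not pass in males (adjusted p = 0.064). Examples were Idh2 (-0.83 and -0.20 n.s., SE 0.07), Pdk2 (-0.55 and -0.30, SE 0.07) and Sdhc (-0.59 and -0.30, SE 0.08), and the abundant Ogdh (-0.17 n.s. and 0.17 n.s., SE 0.08) did not pass. Ketone body metabolism had 8 tested genes, of which 2 rose and 2 fell in females (4 passing adjusted over the list alone) and 2 rose and 1 fell in males (3 passing). The ketone list did not pass camera in females (adjusted p = 0.63) or in males (adjusted p = 0.44). Acetoacetyl-CoA thiolase, Acat1 (-0.38 and -0.29, SE 0.07), fell, and the monocarboxylate transporter Slc16a7 (0.41 and 1.07, SE 0.13) rose. Hydroxybutyrate dehydrogenase, Bdh1 (-0.36 and 0.38, SE 0.11), passed in opposite directions. Breakdown of branched-chain amino acids had 20 tested genes, of which 1 rose and 16 fell in females (17 passing adjusted over the list alone) and 0 rose and 6 fell in males (9 passing). By camera the branched-chain list ranked below the other genes in females (adjusted p = 8.5e-07, or adjusted p = 0.25 with an estimated correlation) and in males (adjusted p = 1.2e-04, or adjusted p = 0.31 with an estimated correlation). Falls included Ivd (-1.16 and -0.63, SE 0.09), Acadsb (-0.64 and -0.36, SE 0.07) and Aldh6a1 (-0.58 and -0.36, SE 0.07).

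The nuclear-encoded respiratory chain had 46 tested genes, of which 0 rose and 14 fell in females (14 passing adjusted over the list alone) and 0 rose and 8 fell in males (14 passing). By camera the nuclear-encoded list ranked below the other genes in females (adjusted p = 0.0037, or adjusted p = 0.65 with an estimated correlation) and in males (adjusted p = 1.2e-04, or adjusted p = 0.54 with an estimated correlation). Falls included the complex I subunits Ndufs7 (-0.66 and -0.35, SE 0.07) and Ndufv1 (-0.51 and -0.27, SE 0.06) and the cytochrome oxidase subunit Cox7a1 (-0.92 and -0.52, SE 0.13), while the ATP synthase gene Atp5b (-0.16 n.s. and 0.04 n.s., SE 0.08) did not pass. Mitochondrially encoded genes had 13 tested genes, of which 7 rose and 0 fell in females (8 passing adjusted over the list alone) and 4 rose and 0 fell in males (7 passing). By camera the mitochondrially encoded list ranked above the other genes in females (adjusted p = 0.0019, or adjusted p = 0.46 with an estimated correlation) and in males (adjusted p = 2.3e-04, or adjusted p = 0.46 with an estimated correlation). The complex I subunits mt-Nd2 (0.80 and 0.70, SE 0.13), mt-Nd4l (0.58 and 0.72, SE 0.15) and mt-Nd1 (0.51 and 0.50, SE 0.15) rose, and mt-Co1 (0.20 n.s. and 0.19 n.s., SE 0.18) did not pass. The share of reads from these genes moved the same way, from 27.9 ± 0.416% in WT females to 33.5 ± 3.82% in LCHADD females and from 30.7 ± 1.76% to 35.4 ± 0.917% in males (SD, n = 3). Strand use in the counting is not stated, so reads from overlapping genes on opposite strands of the mitochondrial genome may not have been told apart.

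**Figure D2:**
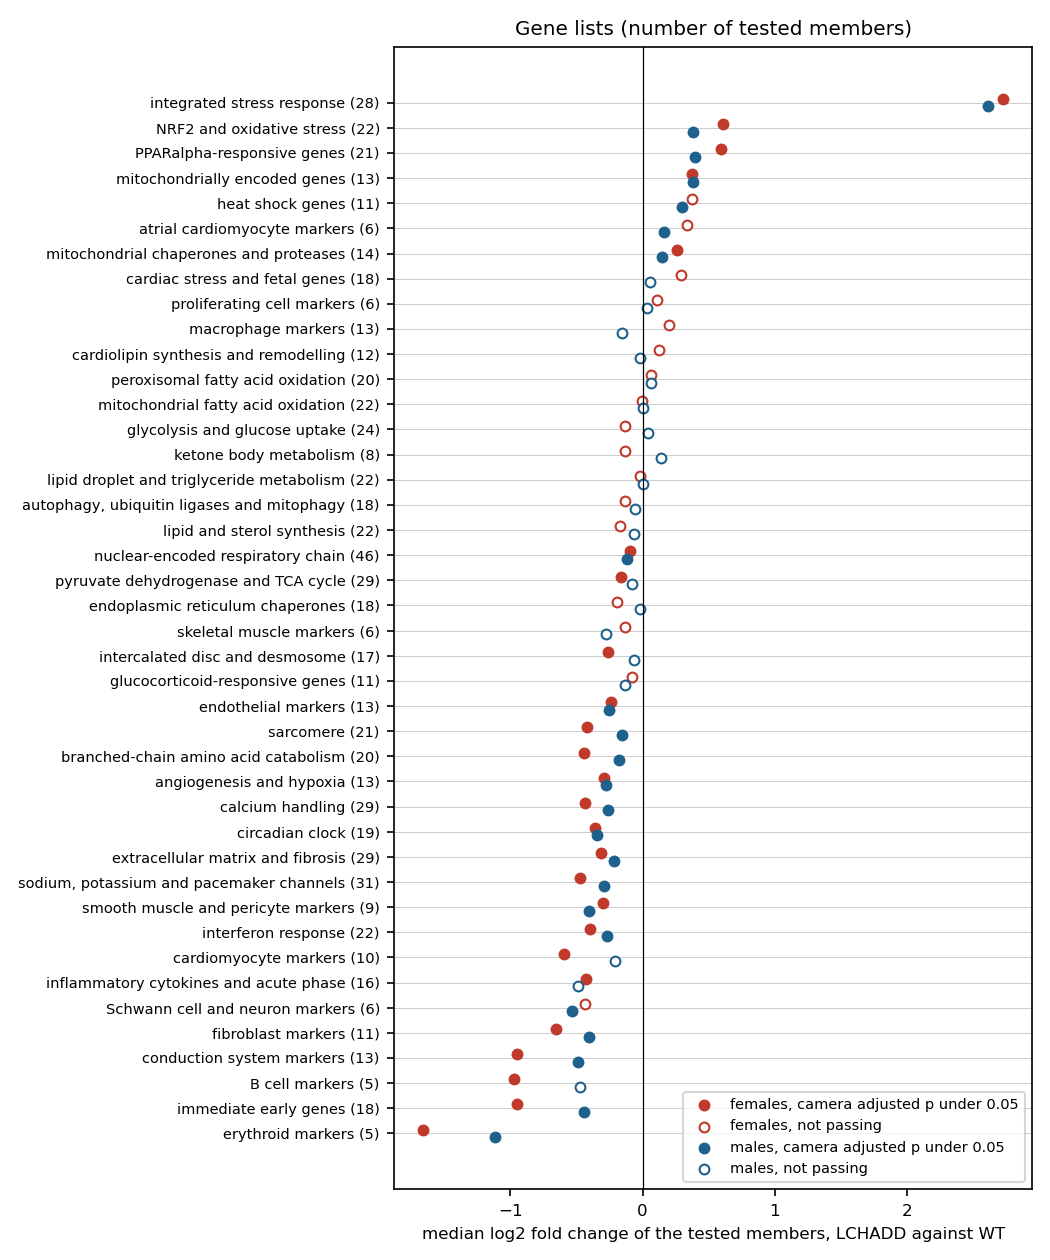
Median log2 change of the tested members of each list, LCHADD against WT, in females (red) and males (blue), with the number of tested members in brackets. Filled points passed camera with its preset correlation (25 of 44 lists in females and 23 in males), of which 0 passed with an estimated correlation, and the X- and Y-linked lists are not drawn.

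Sarcomere genes, which encode the contractile filaments, had 21 tested genes, of which 0 rose and 16 fell in females (17 passing adjusted over the list alone) and 0 rose and 5 fell in males (6 passing). By camera the sarcomere list ranked below the other genes in females (adjusted p = 1.5e-06, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 0.0082, or adjusted p = 0.56 with an estimated correlation). Cardiac troponin I, Tnni3 (-0.68 and -0.34, SE 0.08), tropomyosin, Tpm1 (-0.71 and -0.45, SE 0.10), and Tcap (-1.05 and -0.86, SE 0.19) fell, alpha myosin heavy chain, Myh6 (-0.69 and -0.15 n.s., SE 0.14), was lower in females, and Mybpc3 (-0.29 n.s. and 0.20 n.s., SE 0.13) did not pass. Cardiac stress and fetal genes had 18 tested genes, of which 5 rose and 3 fell in females (8 passing adjusted over the list alone) and 3 rose and 0 fell in males (3 passing). The fetal list did not pass camera in females (adjusted p = 0.39) or in males (adjusted p = 0.46). Skeletal alpha-actin, Acta1 (2.93 and 0.63, SE 0.20), Ankrd1 (1.84 and 1.25, SE 0.24) and the cell cycle inhibitor Cdkn1a (1.83 and 1.92, SE 0.37) rose, Ccn2 (-1.30 and -0.19 n.s., SE 0.20) was lower in females, and the natriuretic peptide gene Nppb (-0.04 n.s. and 0.11 n.s., SE 0.24) did not pass. Sodium, potassium and pacemaker channels had 31 tested genes, of which 2 rose and 21 fell in females (24 passing adjusted over the list alone) and 3 rose and 12 fell in males (17 passing). By camera the ion channel list ranked below the other genes in females (adjusted p = 4.7e-05, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 0.0015, or adjusted p = 0.46 with an estimated correlation). The pacemaker channel Hcn4 (-2.59 and -2.04, SE 0.19) and the potassium channel Kcnk3 (-0.64 and -0.31, SE 0.08) fell, Hcn2 (1.07 and 0.71, SE 0.14) and Kcne1 (1.46 and 2.69, SE 0.31) rose, and connexin 43, Gja1 (-0.22 n.s. and 0.04 n.s., SE 0.09), did not pass. Calcium handling had 29 tested genes, of which 3 rose and 19 fell in females (24 passing adjusted over the list alone) and 3 rose and 10 fell in males (18 passing). By camera the calcium list ranked below the other genes in females (adjusted p = 4.7e-05, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 0.0066, or adjusted p = 0.49 with an estimated correlation). Falls included the calcium channel subunit Cacna2d1 (-1.14 and -0.94, SE 0.12), junctophilin, Jph2 (-0.69 and -0.29, SE 0.07), and Hrc (-1.29 and -0.58, SE 0.15) and Casq1 (-2.45 and -1.98, SE 0.30). The calcium pump Atp2a2 (-0.63 and -0.23 n.s., SE 0.10) was lower in females, the exchanger Slc8a1 (0.30 and 0.45, SE 0.11) rose, and Ryr2 (-0.40 n.s. and -0.08 n.s., SE 0.17) and Cacna1c (-0.32 n.s. and 0.04 n.s., SE 0.18) did not pass. Intercalated disc and desmosome genes had 17 tested genes, of which 0 rose and 7 fell in females (7 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). By camera the intercalated disc list ranked below the other genes in females (adjusted p = 0.0036, or adjusted p = 0.32 with an estimated correlation) and did not pass in males (adjusted p = 0.26). Vinculin, Vcl (-0.48 and -0.09 n.s., SE 0.09), and Tmem65 (-0.53 and -0.25 n.s., SE 0.11) and Dsc2 (-0.53 and -0.17 n.s., SE 0.11) were lower in females, and Dsp (-0.18 n.s. and 0.05 n.s., SE 0.09) did not pass.

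Markers of the conduction system had 13 tested genes, of which 0 rose and 7 fell in females (7 passing adjusted over the list alone) and 0 rose and 4 fell in males (4 passing). By camera the conduction list ranked below the other genes in females (adjusted p = 6.2e-04, or adjusted p = 0.30 with an estimated correlation) and in males (adjusted p = 6.9e-04, or adjusted p = 0.23 with an estimated correlation). Besides Hcn4 and Cntn2, the transcription factor genes Tbx5 (from 553 ± 38.0 to 279 ± 56.0 normalised reads in females and from 524 ± 31.6 to 322 ± 6.72 in males) and Etv1 (-1.06 and -0.78, SE 0.22) fell, and Nkx2-5 (0.03 n.s. and 0.02 n.s., SE 0.12) did not pass. Atrial cardiomyocyte markers had 6 tested genes, of which 2 rose and 0 fell in females (3 passing adjusted over the list alone) and 3 rose and 0 fell in males (3 passing). By camera the atrial list ranked above the other genes in males (adjusted p = 0.041, or adjusted p = 0.23 with an estimated correlation) and did not pass in females (adjusted p = 0.17). In males the median log2 change of the list was 0.16 and the mean 0.85, which Bmp10 raised. The atrial markers Sln, Myl7, Mybphl and Fgf12 were not tested, with at most 7.40 normalised reads in any library. Rises included those of Bmp10 (4.15 and 4.06, SE 0.38) and Pam (0.54 and 0.32, SE 0.08), and the abundant Nppa (0.22 n.s. and -0.12 n.s., SE 0.29) did not pass. Skeletal muscle markers had 6 tested genes, of which 1 rose and 2 fell in females (3 passing adjusted over the list alone) and 1 rose and 0 fell in males (3 passing). The skeletal muscle list did not pass camera in females (adjusted p = 0.77) or in males (adjusted p = 0.44). Acta1 rose, and Tnni2 (-1.58 and -1.50 n.s., SE 0.55) was lower in females. Ckm (-0.28 and -0.05 n.s., SE 0.10) passed in females with limma but not with edgeR (adjusted p = 0.057) or DESeq2 (adjusted p = 0.055). Extracellular matrix and fibrosis genes had 29 tested genes, of which 2 rose and 15 fell in females (18 passing adjusted over the list alone) and 1 rose and 7 fell in males (9 passing). By camera the matrix list ranked below the other genes in females (adjusted p = 0.0037, or adjusted p = 0.41 with an estimated correlation) and in males (adjusted p = 0.0073, or adjusted p = 0.49 with an estimated correlation). Falls included those of Timp2 (-0.92 and -0.75, SE 0.08), Col5a1 (-0.67 and -0.62, SE 0.10) and Fbn1 (-0.61 and -0.45, SE 0.11), while Sparc (-0.08 n.s. and -0.20 n.s., SE 0.10) did not pass. Inflammatory cytokines and acute phase genes had 16 tested genes, of which 0 rose and 4 fell in females (3 passing adjusted over the list alone) and 0 rose and 2 fell in males (2 passing). By camera the cytokine list ranked below the other genes in females (adjusted p = 0.045, or adjusted p = 0.32 with an estimated correlation) and did not pass in males (adjusted p = 0.064). Complement C3 (-1.46 and -0.86, SE 0.14) fell. Interferon response genes had 22 tested genes, of which 1 rose and 8 fell in females (9 passing adjusted over the list alone) and 1 rose and 3 fell in males (5 passing). By camera the interferon list ranked below the other genes in females (adjusted p = 0.0043, or adjusted p = 0.34 with an estimated correlation) and in males (adjusted p = 0.0073, or adjusted p = 0.46 with an estimated correlation). Lower members included Gbp3 (-0.88 and -0.77, SE 0.22), while Ifit2 (0.50 and 0.47, SE 0.13) rose.

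Genes of autophagy, ubiquitin ligases and mitophagy had 18 tested genes, of which 4 rose and 7 fell in females (11 passing adjusted over the list alone) and 3 rose and 3 fell in males (9 passing). The autophagy list did not pass camera in females (adjusted p = 0.14) or in males (adjusted p = 0.50). The mitophagy kinase Pink1 (-1.01 and -0.55, SE 0.08) and Ulk1 (-0.55 and -0.32, SE 0.08) fell, and Gabarapl1 (0.53 and 0.49, SE 0.08) and Ctsl (1.68 and 1.16, SE 0.25) rose. Angiogenesis and hypoxia genes had 13 tested genes, of which 1 rose and 5 fell in females (7 passing adjusted over the list alone) and 1 rose and 3 fell in males (5 passing). By camera the angiogenesis list ranked below the other genes in females (adjusted p = 0.014, or adjusted p = 0.23 with an estimated correlation) and in males (adjusted p = 0.037, or adjusted p = 0.23 with an estimated correlation). Oxygen-sensing genes Egln3 (-1.46 and -1.05, SE 0.10) and Epas1 (-0.50 and -0.32, SE 0.07) fell, Hif1a (0.54 and 0.63, SE 0.12) rose, and Vegfa (-0.20 n.s. and 0.06 n.s., SE 0.09) did not pass. Circadian clock genes had 19 tested genes, of which 1 rose and 7 fell in females (10 passing adjusted over the list alone) and 0 rose and 3 fell in males (6 passing). By camera the clock list ranked below the other genes in females (adjusted p = 0.016, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 0.012, or adjusted p = 0.36 with an estimated correlation). Lower members included Hlf (-1.94 and -1.25, SE 0.26), Nr1d1 (-0.80 and -0.34, SE 0.11) and Arntl (-1.14 and -0.84, SE 0.27). Immediate early genes, which respond within minutes to stimuli and to handling of tissue, had 18 tested genes, of which 0 rose and 12 fell in females (13 passing adjusted over the list alone) and 0 rose and 4 fell in males (4 passing). By camera the immediate early list ranked below the other genes in females (adjusted p = 2.1e-04, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 0.0078, or adjusted p = 0.46 with an estimated correlation). Falls included Nr4a1 (-2.42 and -1.53, SE 0.31), Dusp1 (-1.31 and -0.79, SE 0.23) and Btg2 (-1.21 and -0.93, SE 0.24). Glucocorticoid-responsive genes had 11 tested genes, of which 2 rose and 4 fell in females (6 passing adjusted over the list alone) and 2 rose and 2 fell in males (5 passing). The glucocorticoid list did not pass camera in females (adjusted p = 0.56) or in males (adjusted p = 0.49). Rises of Mt1 (0.59 and 0.37, SE 0.07) and of Cdkn1a stood beside falls of Tsc22d3 (-0.58 and -0.49, SE 0.10) and Pik3r1 (-0.73 and -0.45, SE 0.11).

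Cardiomyocyte markers had 10 tested genes, of which 0 rose and 8 fell in females (10 passing adjusted over the list alone) and 0 rose and 2 fell in males (2 passing). By camera the cardiomyocyte list ranked below the other genes in females (adjusted p = 1.0e-04, or adjusted p = 0.34 with an estimated correlation) and did not pass in males (adjusted p = 0.053). Several belong to the sarcomere list too, such as Tnni3 and Myh6, and Pln (-0.59 and -0.35 n.s., SE 0.15) was lower in females. Fibroblast markers had 11 tested genes, of which 0 rose and 10 fell in females (10 passing adjusted over the list alone) and 0 rose and 5 fell in males (7 passing). By camera the fibroblast list ranked below the other genes in females (adjusted p = 7.4e-06, or adjusted p = 0.22 with an estimated correlation) and in males (adjusted p = 4.4e-05, or adjusted p = 0.18 with an estimated correlation). Examples were Gsn (-0.90 and -0.49, SE 0.09), Dcn (-0.65 and -0.54, SE 0.07) and Dpep1 (-0.83 and -0.56, SE 0.11). Endothelial markers had 13 tested genes, of which 0 rose and 6 fell in females (6 passing adjusted over the list alone) and 0 rose and 5 fell in males (7 passing). By camera the endothelial list ranked below the other genes in females (adjusted p = 0.0036, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 3.9e-04, or adjusted p = 0.23 with an estimated correlation). Examples were Tek (-0.74 and -0.57, SE 0.09), Pecam1 (-0.47 and -0.34, SE 0.06) and Cdh5 (-0.37 and -0.41, SE 0.08). Smooth muscle and pericyte markers had 9 tested genes, of which 0 rose and 3 fell in females (3 passing adjusted over the list alone) and 0 rose and 5 fell in males (7 passing). By camera the smooth muscle list ranked below the other genes in females (adjusted p = 0.044, or adjusted p = 0.36 with an estimated correlation) and in males (adjusted p = 1.9e-04, or adjusted p = 0.23 with an estimated correlation). Falls included Notch3 (-0.39 and -0.41, SE 0.10) and Vtn (-0.53 and -0.69, SE 0.14). Macrophage markers had 13 tested genes, of which 3 rose and 0 fell in females (3 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). The macrophage list did not pass camera in females (adjusted p = 0.21) or in males (adjusted p = 0.47). In females Lyz2 (0.61 and -0.12 n.s., SE 0.18) and Cd68 (0.66 and -0.20 n.s., SE 0.21) were higher. B cell markers had 5 tested genes, of which 0 rose and 4 fell in females (5 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). By camera the B cell list ranked below the other genes in females (adjusted p = 0.024, or adjusted p = 0.25 with an estimated correlation) and did not pass in males (adjusted p = 0.25). In females Ighm (-0.52 and -0.47 n.s., SE 0.16) and Igkc (-0.92 and -0.54 n.s., SE 0.30) were lower. Schwann cell and neuron markers had 6 tested genes, of which 0 rose and 2 fell in females (2 passing adjusted over the list alone) and 0 rose and 1 fell in males (2 passing). By camera the Schwann cell list ranked below the other genes in males (adjusted p = 0.012, or adjusted p = 0.23 with an estimated correlation) and did not pass in females (adjusted p = 0.15). Dopamine beta-hydroxylase, Dbh (-4.25 and -3.80, SE 0.39), an enzyme of sympathetic neurons, fell from 74.1 ± 12.3 to 3.93 ± 2.06 normalised reads (SD, n = 6). Of the other neuron genes in the list, Th had 0 reads in every library, and Snap25 and Prph had at most 0.867 and 3.46 normalised reads. They were not tested, so the fall of Dbh alone does not stand for neurons. Erythroid markers had 5 tested genes, of which 0 rose and 5 fell in females (5 passing adjusted over the list alone) and 0 rose and 5 fell in males (5 passing). By camera the erythroid list ranked below the other genes in females (adjusted p = 1.8e-04, or adjusted p = 0.32 with an estimated correlation) and in males (adjusted p = 1.3e-04, or adjusted p = 0.31 with an estimated correlation). The heme synthesis enzyme Alas2 (-1.82 and -1.12, SE 0.23) fell with the globin genes Hba-a2 (-1.71 and -1.10, SE 0.23) and Hbb-bt (-1.42 and -1.25, SE 0.25), whose copies may share reads.

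Proliferating cell markers had 6 tested genes, of which 0 rose and 0 fell in females (0 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). The proliferation list did not pass camera in females (adjusted p = 0.68) or in males (adjusted p = 0.96). The proliferation marker Mki67 (0.11 n.s. and 0.04 n.s., SE 0.26) was among them. Fewer than 4 members of 6 lists passed the filter, so no list test was run on them. Neutrophil markers had 3 tested genes, of which 0 rose and 0 fell in females (0 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). The values of Csf3r (0.10 n.s. and 0.16 n.s., SE 0.39) are an example. T and NK cell markers had 3 tested genes, of which 0 rose and 0 fell in females (0 passing adjusted over the list alone) and 0 rose and 0 fell in males (1 passing). Here Cd4 (0.73 n.s. and -0.96 n.s., SE 0.62) did not pass. White and brown adipocyte markers had 2 tested genes, of which 1 rose and 1 fell in females (2 passing adjusted over the list alone) and 1 rose and 0 fell in males (1 passing). Cidea (0.60 and 0.39, SE 0.12) rose, and Cfd was lower in females (-2.81, SE 0.82). Epicardium and mesothelium markers had 3 tested genes, of which 1 rose and 0 fell in females (1 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). Krt8 had 63 reads against 2 reads over the 3 WT female libraries, a ratio of 39.2 (95% counting interval 10.4 to 331). Female-specific X genes had 1 tested gene, of which 0 rose and 0 fell in females (1 passing adjusted over the list alone) and 0 rose and 0 fell in males (1 passing). Tsix, the other member of that list, was not tested. None of the 6 lung markers passed the filter. No list that passed camera had a median and a mean of opposite sign. Among the other lists tested, the median and the mean differed in sign for ketone body metabolism (-0.13 and 0.08), cardiolipin (0.12 and -0.06), skeletal muscle (-0.13 and 0.17) and sterol synthesis (-0.17 and 0.0044) in females, and for endoplasmic reticulum chaperones (-0.02 and 0.03) and autophagy (-0.06 and 0.02) in males.

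**Figure D3:**
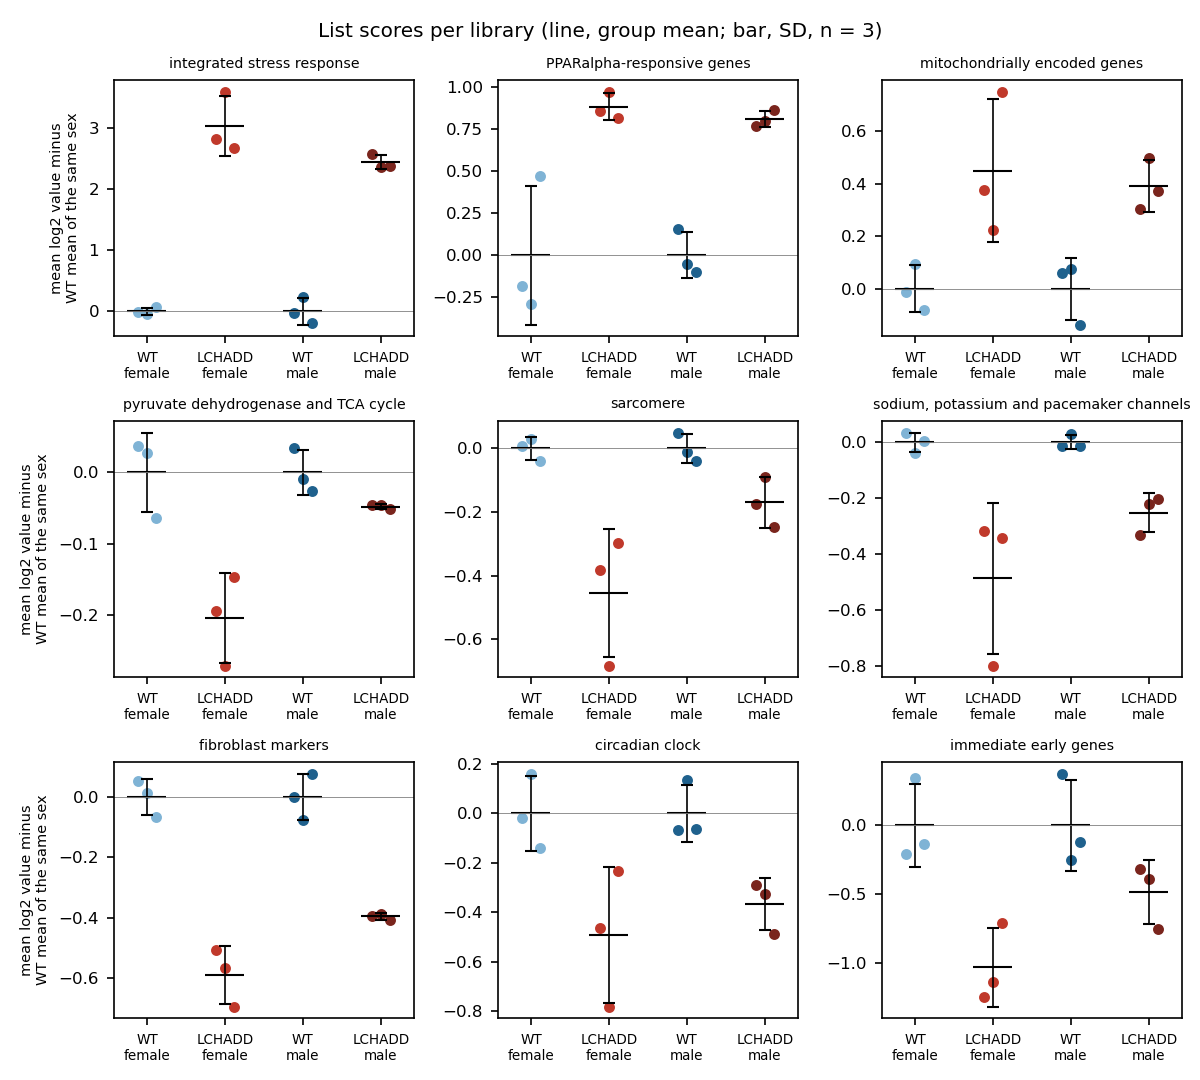
Mean log2 value of 9 lists in each of the 12 libraries, less the WT mean of the same sex. Points are libraries, lines are group means and bars are SD (n = 3).

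The changes in females and males went together across genes. Pearson's correlation of the log2 changes was 0.821 and Spearman's 0.728 across 13865 genes, which are not independent replicates, and Pearson's was 0.900 for genes with a mean of at least 50. Of the 1862 genes that passed in both sexes, 1860 changed in the same direction, 932 higher and 928 lower in LCHADD, against 178 and 185 for independent lists of these sizes. The WT and LCHADD libraries of each sex are separate, so the sexes share no control library. Bdh1 passed in opposite directions, and the difference between the sexes did not pass (adjusted p = 0.14). Of the 2146 genes that passed in males, 99.2% had the same sign in females. Among the genes that passed in both sexes the change was larger in females for 1468. With no filter on low values the correlation was 0.541.

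**Figure D4:**
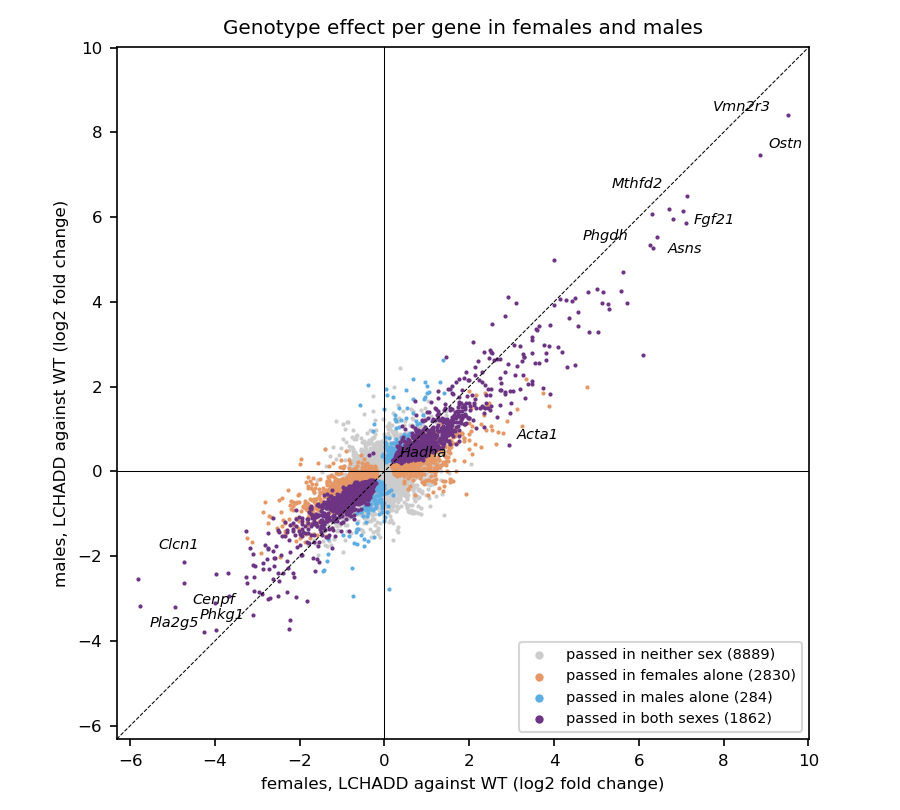
Log2 change of each of the 13865 tested genes, LCHADD against WT, in females (horizontal axis) and males (vertical axis), with a dashed line of equal change. Colours show whether a gene passed in both sexes (1862), in females alone (2830), in males alone (284) or in neither (8889).

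The interaction asks whether the genotype changed a gene differently in females and males. Acta1, the skeletal muscle alpha-actin that is also made in the fetal and stressed heart, passed. It went from 1736 ± 303 to 13097 ± 456 normalised reads in females and from 4886 ± 1042 to 7707 ± 2370 in males (SD, n = 3). The log2 change was 2.93 in females and 0.63 in males, a difference of 2.30 (SE 0.29, limma adjusted p = 0.011). No other gene passed, while 1363 had an unadjusted p under 0.05. Of the 44 lists, 18 passed camera for the interaction, 4 with changes that were more positive in females (the integrated stress response, NRF2, macrophage and skeletal muscle lists) and 14 with changes that were more negative, the sarcomere, branched-chain amino acid and cardiomyocyte lists among them. With an estimated correlation 0 passed, the lowest adjusted p being 0.35, and fry passed 2, ketone body metabolism (adjusted p = 0.030) and B cell markers (adjusted p = 0.0096). With robust eBayes Acta1 did not pass (adjusted p = 0.11) and the isocitrate dehydrogenase gene Idh2 was the 1 gene that did. The count of genes was 126 with DESeq2, 2 with edgeR and 749 with array quality weights. It rose to 186 without LCHADD female 3, 69 without LCHADD male 3, 8 without LCHADD female 2 and 2 without WT male 1, and was 0 without WT female 2, WT female 3, WT male 2 or LCHADD female 1.

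Between WT females and WT males, 34 genes differed, 13 higher and 21 lower in females, with 1019 at an unadjusted p under 0.05. Xist had 2012 ± 56.3 normalised reads in WT females and 0.909 ± 0.868 in WT males, and the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d had 1436 ± 96.7, 787 ± 23.0, 349 ± 27.2 and 259 ± 8.56 in WT males (SD, n = 3). Also higher in females were the matricellular gene Ccn2 (log2 difference 1.15, SE 0.20), the collagen gene Col14a1 (1.09, SE 0.21), Kdm6a, which escapes X inactivation (0.89, SE 0.10), and Slc16a7 (0.80, SE 0.13). The complement gene C7 was lower in females (-3.27, SE 0.23). The count was 17 without WT female 2, 20 without WT female 3, 17 without WT male 1, 17 without WT male 2, 105 without LCHADD female 2 and 56 without LCHADD female 3. With the 6 WT libraries alone in the fit it was 142, with DESeq2 87, with array quality weights 133, and without LCHADD female 2 and WT female 3 73.

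Between LCHADD females and LCHADD males, 800 genes differed, 368 higher and 432 lower in females, 311 of them by at least 1.5-fold, with 2935 at an unadjusted p under 0.05. With scaling by reads from nuclear genes the balance turned, to 500 higher and 258 lower of 758. Xist had 3986 ± 535 normalised reads in LCHADD females and 4.27 ± 4.46 in LCHADD males. Also higher in females were Serpinb1c (log2 difference 2.60, SE 0.61), Ccn4 (2.20, SE 0.53), the activin gene Inhba (2.04, SE 0.53) and the keratin gene Krt18 (1.93, SE 0.49). Ddx3y, Eif2s3y, Uty and Kdm5d had 1432 ± 135, 1020 ± 60.9, 356 ± 15.5 and 246 ± 7.82 in LCHADD males, and the methyltransferase gene Inmt was lower in females (-2.66, SE 0.66). The list of Y-linked genes had 4 tested genes, of which 0 rose and 0 fell in females (0 passing adjusted over the list alone) and 0 rose and 0 fell in males (0 passing). The Y-linked list did not pass camera in males (adjusted p = 0.76). In females its genes had 0 reads in every library, so no change could be found there. Eif2s3y did not pass in males with limma (log2 change 0.37, adjusted p = 0.25) but rose with edgeR (adjusted p = 0.018) and DESeq2 (adjusted p = 0.0046). Genes of the X chromosome that escape inactivation had 4 tested genes, of which 2 rose and 0 fell in females (2 passing adjusted over the list alone) and 2 rose and 0 fell in males (2 passing). The escape list did not pass camera in females (adjusted p = 0.55) or in males (adjusted p = 0.34). The translation factor gene Eif2s3x (0.40 and 0.45, SE 0.08) and Kdm5c (0.24 and 0.27, SE 0.09) rose with the LCHADD genotype. Xist went from 2012 ± 56.3 to 3986 ± 535 in females, which did not pass (log2 change 0.98, SE 0.44, limma adjusted p = 0.10), but passed with edgeR (adjusted p = 3.3e-05) and DESeq2 (adjusted p = 4.6e-16). The count of genes that differed between the sexes in LCHADD was 82 with the 6 LCHADD libraries alone in the fit and 3121 with array quality weights. It was 426 without LCHADD female 1, 387 without LCHADD male 1, 215 without LCHADD male 2 and 1643 without LCHADD female 3.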

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

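All tests of explanations in this part were chosen after the result they address was seen, except the splits of the libraries behind the counts of genes and lists and the tests that leave out LCHADD female 2 and thin the reads.

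Acta1 differed between the sexes by the test of the interaction, its change in females exceeding that in males by 2.30 on the log2 scale (limma adjusted p = 0.011). With robust eBayes it did not pass (adjusted p = 0.11) and Idh2 alone did. Its normalised reads were higher in all 3 LCHADD females than in all 3 WT females, while LCHADD male 3 (5000) lay within the range of WT males (3730 to 5755). Camera gave a difference between the sexes, with its preset correlation, for 18 lists. Changes were more positive in females for the integrated stress response (adjusted p = 6.8e-07), NRF2 and oxidative stress (9.7e-04), macrophage markers (0.0072) and skeletal muscle markers (0.050). They were more negative in females for sarcomere genes (adjusted p = 6.8e-07), branched-chain amino acid catabolism (2.2e-06), cardiomyocyte markers (1.7e-05), pyruvate dehydrogenase and the tricarboxylic acid cycle (3.5e-05), glycolysis (2.9e-04), calcium handling (2.9e-04) and ion channels (7.5e-04). The same held for the intercalated disc (adjusted p = 0.0015), immediate early genes (0.0039), fibroblast markers (0.0072), autophagy (0.044), angiogenesis (0.044), erythroid markers (0.044) and ketone body metabolism (0.050). With an estimated correlation none of the 18 passed, the adjusted p lying between 0.35 and 0.57. In 100 splits of the libraries, 19 gave as many lists and 6 gave as many genes, the highest others being 23 lists and 606 genes, so chance is not excluded for either count.

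More genes passed in females (4692) than in males (2146), and more differed between the sexes in LCHADD (800) than in WT (34). With the compared groups alone in the fit the counts were 3436 and 3342, and 82 in LCHADD against 142 in WT. Both patterns therefore depend on which groups are in the fit. Libraries of LCHADD females differed most from each other. The chi-square per gene between pairs of them was 21.7 to 55.0, against 4.73 to 14.9 within the other groups. The fit with all groups shares 1 spread per gene, which understates the spread of LCHADD females and overstates that of the others. Read depth is argued against for the female and male counts: with every library thinned to 10.5 M reads (M, mega) from nuclear genes, 4605 genes passed in females and 2008 in males. Without LCHADD female 2, the library farthest along the main component, 4269 passed in females and 3293 in males, so that library may carry part of the difference. Along the axis of the mean genotype effect, the effect was 1.13 in females and 0.866 in males, and a share of 0.085 of the 200 splits of the sex labels gave a difference as large. Whether the genotype acts more strongly in females stays open.

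Markers of fibroblasts, endothelial cells and smooth muscle were lower in LCHADD, 25 of 33 falling and 0 rising in the mean of both sexes. An equally lower share of all cells other than cardiomyocytes is argued against by the macrophage markers alone, whose score (each library's median over the markers, log2) changed by 0.06, 0.44 above that of the 3 types (SE 0.08), and by sex in females (0.59, SE 0.12) and in males (0.29, SE 0.12), where the macrophage score itself changed by -0.09, while 5 of 5 erythroid, 4 of 5 B cell and 3 of 6 Schwann cell and neuron markers fell in the mean of both sexes, so a lower share of most such cells stays open. The score of the 3 types changed by -0.38 as deposited and -0.34 (SE 0.04) under the scaling that brought it nearest to 0. The scalings differed too little to test scaling as a cause. The score of the cardiomyocyte markers changed by -0.41 (SE 0.09); in females 8 of 10 fell (median log2 change -0.59), against 2 in males (median -0.21), a difference between the sexes that did not pass camera with an estimated correlation (adjusted p = 0.37). Lower expression within each cell type, or fewer cells of some types, may both be at work and were not separated in bulk tissue.

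In the mean of both sexes 9 of 19 clock genes fell and 1 rose, and 12 of 18 immediate early genes fell and 0 rose (3 and 4 fell in males), and neither list passed camera with an estimated correlation (adjusted p = 0.30 and 0.33). A different hour of collection alone was taken to move the limbs of the clock in opposite directions. Both lay below 0. Arntl, Npas2 and Clock did so by a mean of -0.40 (SE 0.15), and 2 of them fell. The 9 genes of the opposite limb did so by -0.61 (SE 0.22), of which 4 fell and 0 rose. The assumption about the limbs was set after the values were seen and was not tested, so the hour stays open. The mean over the immediate early genes differed by -0.76 (SE 0.17, exact p = 0.005, the smallest the 400 splits can give). It ranged from -1.12 to -0.33 in LCHADD and from -0.62 to 0.72 in WT. Handling that differed between the genotypes could give this as well as the genotype could, and the labels record neither the hour nor the handling.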

How the results depend on the processing

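Nuclear-read scaling and leaving out WT female 3 with LCHADD female 2 were chosen after seeing the data, and the other alternatives before. No named gene or list that passed changed direction under an alternative in which it also passed. With the compared groups alone in the fit, fewer genes differed between the sexes in LCHADD than in WT, the opposite of the order with all groups, and robust eBayes replaced Acta1 by Idh2 as the 1 gene of the interaction. Beyond those given here, no count of genes or lists moved by more than 1.5 times, and Hadha and Hadhb kept their side of the threshold. The cause of these changes was not tested.

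Leaving out 1 library at a time, the genes passing were 3733 to 5075 in females (4692 with all 12 libraries), 1317 to 3293 in males (2146), 5019 to 6033 in the mean of both sexes (5661), 0 to 186 for the interaction (1), 17 to 105 between the sexes in WT (34) and 215 to 1643 in LCHADD (800). The lists passing were 23 to 25 in females (25 with all 12), 19 to 25 in males (23), 24 to 27 in the mean (26) and 15 to 20 for the interaction (18). The correlation between the sexes was 0.783 to 0.822. Hadha changed by 0.12 to 0.20 in females, passing without LCHADD female 3 (0.20), and by 0.15 to 0.22 in males and 0.15 to 0.19 in the mean. Hadhb changed by 0.21 to 0.28 in females and 0.24 to 0.30 in males, losing its call without WT female 2 (0.21, adjusted p = 0.070) and, in males, without WT male 2 (0.24, adjusted p = 0.073), WT male 3 (0.27, adjusted p = 0.062), LCHADD male 1 (0.28, adjusted p = 0.052) and LCHADD male 3 (0.25, adjusted p = 0.053). Counts that moved by over 1.5 times were, in males, 1332 without WT male 1, 1317 without WT male 3, 3293 without LCHADD female 2 and 1317 without LCHADD male 1. For the interaction they were 0 without WT female 2, 0 without WT female 3, 2 without WT male 1, 0 without WT male 2, 0 without LCHADD female 1, 8 without LCHADD female 2, 186 without LCHADD female 3 and 69 without LCHADD male 3. Between the sexes in WT they were 17 without WT female 2, 20 without WT female 3, 17 without WT male 1, 17 without WT male 2, 105 without LCHADD female 2 and 56 without LCHADD female 3, and in LCHADD 426 without LCHADD female 1, 1643 without LCHADD female 3, 387 without LCHADD male 1 and 215 without LCHADD male 2.

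Requiring at least 1.5-fold left 2461, 1087, 2033 and 311 genes in females, males, the mean and between LCHADD sexes. Array quality weights gave 3601 in males, 749 for the interaction, 133 and 3121 between the sexes in WT and LCHADD. With the compared groups alone in the fit the counts were 3436 in females, 3342 in males, 142 and 82 between the sexes, and this does not apply to the mean or the interaction, which use all 4 groups. DESeq2 gave 126 genes for the interaction and 87 between WT sexes. For the interaction, edgeR, TMM scaling and a filter at 50 gave 2. Leaving out WT female 3 with LCHADD female 2 gave 3317 in males, 9 for the interaction and 73 between WT sexes. Nuclear-read scaling moved the share of higher genes from 49.3% to 59.6% of 4824 in females, from 49.6% to 57.4% of 5758 in the mean of both sexes, and from 46.0% to 66.0% of 758 between the sexes in LCHADD. The estimated correlation left 0 lists in each of the 4 comparisons, and fry passed 2 for the interaction.

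The correlation between the sexes, 0.821, became 0.836 with 5 added, 0.541 without a filter, 0.900 with a filter at 50 and 0.776 without WT female 3 and LCHADD female 2. Hadha passed in females with array weights (log2 change 0.20, adjusted p = 0.0034) and nuclear-read scaling (log2 change 0.22, adjusted p = 0.023), and in males with array weights (log2 change 0.18, adjusted p = 0.035), with the compared groups alone (log2 change 0.18, adjusted p = 0.042) and without WT female 3 and LCHADD female 2 (log2 change 0.18, adjusted p = 0.047). Hadhb lost its call in females with the compared groups alone (log2 change 0.24, adjusted p = 0.069).

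Libraries of the same replicate number share only a number: the deviations of same-numbered libraries from their group means correlated at -0.106 to 0.0491 over 18 pairs, and 3 of 12 libraries correlated best with their own number. With the number as a block, 4502, 2016 and 5482 genes passed in females, males and the mean, 1 for the interaction, and 31 and 541 between the sexes in WT and LCHADD. The block changed no call of Hadha or Hadhb and gave 25, 22, 26 and 17 lists.

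Of the genes that passed, edgeR shared 99.0% in females and 96.8% in males, and DESeq2 97.9% and 97.3%, all with the same sign. Of the named genes, edgeR did not pass Arntl in males (adjusted p = 0.056), Ckm in females (adjusted p = 0.057), Inhba in males (adjusted p = 0.072), Kdm5c in males (adjusted p = 0.054) and Vldlr in males (adjusted p = 0.050), and DESeq2 did not pass Ckm in females (adjusted p = 0.055), Inmt in females (adjusted p = 0.15) and Inmt in the mean (adjusted p = 0.081). One or both of them passed Acadl in the mean, Atp2a2 in males, Atp5b in females, Col14a1 in females, Eif2s3y in males, Eno3 in males, Idh2 in males, Xist in females and mt-Co1 in the mean, which limma did not. Over the genes named in the text, 306 of 7104 results lost their call when a library was left out and 38 gained one. In splits of the 6 libraries of a comparison into 2 groups of 3, 1 of 10 splits, the real one, gave as many genes in females, in males and between the sexes in WT and in LCHADD, the highest other being 0 in each, and 10 splits are too few to test chance. For lists 1 of 10 gave as many in females and in males, the highest others being 17 and 13. For the mean of both sexes 1 of 100 splits, the real one, gave as many genes (highest other 2266). For the correlation between the sexes 1 of 100, the real one, gave as large a value (highest other 0.656). The real split is always among the 100, so these results argue against chance and do not exclude it. Chance is left open for the 26 lists of the mean: 1 of 100 splits gave as many, but the highest other, 25, lies within the range of the counts with 1 library left out. Small effects may be missed at n = 3. Simulation found 46.3% of 1.5-fold changes in females and 20.9% for the interaction, which may not hold here.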

Other observations

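All families and tests in this part were chosen after the gene table was seen.

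Families were taken by gene symbol among protein-coding genes, and no test of them against other genes was made. Among the cytosolic ribosomal proteins, 76 of 79 tested genes rose and 1 fell in females and 67 rose and 1 fell in males, with median log2 changes of 0.94 and 0.48. For the cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs with amino acids, 17 of 20 tested genes rose and 0 fell in females and 13 rose and 0 fell in males, with medians of 1.02 and 0.82. For the subunits of the CCT chaperonin whose symbols begin with Cct, a part of the complex, 6 of 6 tested genes rose and 0 fell in females and 5 rose and 0 fell in males. Of the genes whose symbols begin with Eif, which are initiation factors and regulators of them, kinases and binding proteins among them, 27 of 53 tested genes rose and 0 fell in females and 11 rose and 0 fell in males, and of the proteasome subunits, 21 of 38 tested genes rose and 1 fell in females and 5 rose and 0 fell in males. For the mitochondrial synthetases 1 of 17 tested genes rose and 2 fell in females and 1 rose and 0 fell in males, and for the mitochondrial ribosomal proteins 26 of 77 tested genes rose and 5 fell in females and 5 rose and 0 fell in males. The change of each family's score (each library's median over the family) had the same sign, except for the mitochondrial synthetases, under the deposited, TMM, upper-quartile and nuclear-read scalings in each sex.

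An equal rise of all synthetases is argued against. The cytosolic minus mitochondrial score was higher in LCHADD by 0.94 (SE 0.12, exact p = 0.005, the smallest that the 400 splits of the genotype labels within sex can give). Both families were chosen after their values were seen, so this p is descriptive and no independent support. The ribosomal protein score changed by 0.70 (SE 0.07) in the mean of both sexes under the scaling that brought it nearest to 0. These scalings differed too little to test scaling as a cause.

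Changes near Hadha could come from variants carried along with the altered gene. Of its 40 nearest tested neighbours, in the gene order of GRCm38, 6 changed by at least 1.5-fold in the mean of both sexes, against a median of 6 and a 95th percentile of 10 over all windows of that size. This count neither points to such variants nor excludes them.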
